A study of Mus musculus with 6 samples.

How the data were processed

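RNA from 6 pools of mouse embryo heads at embryonic day 8.5, 3 wild-type and 3 with Sf3b4 deleted in neural crest cells, was sequenced, with 3 heads per pool. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy micro kit and libraries were made with the Illumina TruSeq Standard Total RNA kit. The authors deposited raw counts of reads per gene, 1 file per pool, as whole numbers that were not normalized. The build is mm10, per the submitters' processing notes; the aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here. A gene on the opposite strand, or a near-identical copy, can therefore share the reads of a gene. Each file holds 54532 Ensembl gene IDs, of which 54495 matched GENCODE M21 (GRCm38, the assembly of mm10), from which symbols, coordinates, exon lengths and GC content were taken. Samples were grouped by their titles, which describe the mutants as homozygous nulls, while the genotype entries and the design text speak of a neural crest mutant. The second reading is used here, and how complete the loss was is not given in the sources used here. The 37 mitochondrial genes are listed at 0 in every pool. Of 92 genes chosen by the rule below, 7 share over 10% of their exonic bases with another gene, 4 of them with a gene on the opposite strand.

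Total counts ran from 6930827 to 12251910 per pool. Genes were kept with edgeR's filterByExpr, which left 14008, and scaled by TMM factors. The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-normalised and given as mean ± SD over 3 pools. The design text describes 3 separate pools per genotype, so each was counted as a replicate. Any 2 pools of a genotype differed by more than sampling noise (chi-square per degree of freedom 3.01 to 10.3), which separate libraries nearly always do and which does not show that the pools are independent. Where a genotype held 1 to 3 counts of a gene, the ratio of summed counts is given with an exact 95% interval. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python for the annotation and matplotlib for the plots.

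Before the data were examined, 27 gene lists, the alternatives and the rule for named genes were fixed. The lists cover the SF3B complex and U2 particle, other splicing genes, p53 targets, ATF4 targets, transcripts sensitive to nonsense-mediated decay, neural crest specifiers, crest mesenchyme and arches, chromatin modifiers, Hox genes, WNT and other signalling, apoptosis, the cell cycle, regions of the neural tube, surface ectoderm, mesoderm, heart, endoderm, erythroid cells, endothelium, extraembryonic tissue, mitochondrial genes, immediate early genes, hypoxia, structured RNA and sex-linked genes. Lists with at least 5 tested members, except the sex-linked genes, went through camera with a preset correlation of 0.01 on limma-voom values (two-sided, adjusted over the lists), camera with an estimated correlation, and fry. Of the listed genes, Rnu4atac, Ddit3, Bim, Ahsp, Aldoa, Rmrp, Rn45s and Rprl1 were not analysed here because their symbols matched no single ID. The named genes are Sf3b4 and the SF3B complex; the 12 largest rises and 12 largest falls that passed, with a mean of at least 1 CPM in the higher group, groups that do not overlap and no predicted gene model; up to 4 members of each list that passed, by smallest p, or else the 2 with the smallest p; and Wnt1, Xist and Ddx3y. Of the genes so chosen 5 are left out of the text but stay in the counts. Other list members are named in the text as examples chosen after their values were seen.

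On simulated counts with the real means, library sizes and dispersions, the edgeR step (13805 genes) recovered 62.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 95.5% of those changed 4-fold. Of its 172 calls 14 were false, which is more than the nominal 5 in 100. Of 200 simulated unchanged lists 1.5% had an unadjusted camera p under 0.05, but genes were simulated as independent, so this does not test camera on lists of correlated genes. The alternatives were DESeq2, limma-voom, other scaling factors, other filters on low counts, a fit without robust estimation, library sizes without structured RNA, the replicate number as a block, each pool left out, a threshold of 0.1 and windows of 1 and 10 Mb around Sf3b4. A further 3 alternatives were chosen after seeing the data: Y-linked reads as a covariate, the 4 pools with Y-linked reads alone, and a correction for exon length and GC content, in which the trend of each pool's deviations (splines with 4 degrees of freedom each) was removed as an offset. On simulated data with a length trend of -0.1 per doubling, that correction left a slope of -0.0101.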

Results

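Gene expression was measured by total RNA sequencing in heads of mouse embryos at embryonic day 8.5. Wild-type embryos were compared with embryos in which Sf3b4 was deleted in neural crest cells, the migratory cells that give rise to much of the facial skeleton and the peripheral nervous system. Each sample was a pool of 3 heads, taken before any abnormality of form was visible, and there were 3 pools per genotype. The wild-type pools held 10661159, 6930827 and 11797020 counts and the mutant pools 12251910, 9715400 and 7420956. At these depths 14008 genes were tested. The comparison asked which genes differ in the head when neural crest cells lack SF3B4, a subunit of the SF3B complex that helps the U2 small nuclear ribonucleoprotein recognise the branch site of introns. The labels do not say that the pools of a genotype came from separate litters, so the tests measure the spread between these pools.

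Sf3b4 itself (ENSMUSG00000068856, mm10 chromosome 3, 96172332 to 96177564, plus strand) was read at 77.7, 72.8 and 63.9 CPM (counts scaled to a common library size) in the wild-type pools and at 56.1, 64.2 and 60.9 CPM in the mutant pools. The means were 71.4 ± 6.97 and 60.4 ± 4.09 CPM (SD, n = 3 each), a log2 fold change of -0.24 (SE 0.0918) that did not pass the test (edgeR quasi-likelihood test, adjusted p = 0.128), and the ranges of the groups overlapped. Counts per gene do not show which exons were deleted, and neural crest cells are only part of the head. Sf3b3 and Sf3b1, which encode other subunits of the SF3B complex, rose in all mutant pools, by 0.70 (SE 0.0727) and 0.52 (SE 0.0769) on the log2 scale. Their edgeR adjusted p values were 4.17e-05 and 0.000854. Phf5a (0.27) and Rbm17 (0.25) also passed, whereas Sf3b5, Sf3b6 and Sf3b2 did not, with log2 fold changes of 0.20, 0.19 and 0.00. The calls of Phf5a and Rbm17 were lost without wild-type replicate 2 or any 1 mutant pool. Of 21 tested genes of the SF3B complex and the U2 particle, 4 rose and none fell over all genes tested, and 9 rose and 1 fell when adjusted over the list alone. The list was higher by camera (adjusted p = 0.0023) but not with an estimated correlation between genes (adjusted p = 0.4 with an estimated correlation). Among 59 other spliceosome genes and splicing regulators, 5 rose and 2 fell (8 and 2 when adjusted over the list alone), including Txnl4a (0.62), Ptbp2 (0.43) and Srsf5 (0.34) upward and Srrm2 (-0.48) downward. The calls of Ptbp2 and Srsf5 were lost without mutant replicate 1, and that of Srsf5 also without mutant replicate 3. The camera adjusted p of that list was 0.00907, and 0.772 with an estimated correlation; by fry it was 0.346. It was lost without wild-type replicate 1 (0.145) and without mutant replicate 2 (0.0688).

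Across the transcriptome, 914 genes changed, 371 higher and 543 lower in the mutant pools (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p under 0.05). The changes were mostly modest, with a median of 0.50 on the log2 scale among the genes that rose and 0.45 in size among those that fell. Only 71 genes rose and 53 fell by more than 2-fold. In 913 of the 914 genes the 3 mutant pools lay entirely above or below the 3 wild-type pools, a separation seen in 28.3% of all tested genes and in 10% by chance. The count depended on single pools. It was 230, 392 and 443 without mutant replicate 1, 2 and 3, 367 without wild-type replicate 2 and 1810 without wild-type replicate 3. Wild-type replicate 1 and mutant replicate 3 held 1 count each on Y-linked genes, against 344 to 664 in the other pools. The count was 535 in the 4 pools with Y-linked reads, with 249 genes higher and 286 lower, and 1616 with Y-linked reads as a covariate. A correction for gene length and GC content gave 655 higher and 557 lower genes, so the balance of higher and lower calls depended on it.

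Targets of p53, the transcription factor that answers DNA damage and other cell stress, rose together and were among the largest changes. Of 44 tested targets 29 rose, none fell and 15 did not pass, and 32 rose when adjusted over the list alone. Phlda3, an inhibitor of AKT signalling, went from 1.48 ± 0.48 to 35.4 ± 8.04 CPM, a log2 fold change of 4.60 (SE 0.242, n = 3 pools each, edgeR adjusted p = 4.11e-07). The cell cycle inhibitor Cdkn1a rose by 4.23 (SE 0.372) and Eda2r, a gene of the TNF receptor family, by 4.13 (SE 0.386). Pmaip1 (3.04), Bbc3 (1.05) and Bax (0.59), which encode proteins that promote mitochondrial apoptosis, rose as well. So did Trp53inp1 (2.97), Slc19a2 (2.81), Ccng1 (2.66), Sesn2 (1.83), Ak1 (1.76), Plk2 (1.57), Btg2 (1.34) and Mdm2 (0.80), the last a ligase that degrades p53. The median log2 fold change of the list was 0.77, and it was 0.57 between the pools without Y-linked reads and 0.81 among those with them. Camera gave an adjusted p of 3.56e-29, and the adjusted p was 0.189 with an estimated correlation. The number of targets that rose stayed between 24 and 31 in every alternative setting, with none lower. Of the targets named here only the call of Trp53inp1 was lost with 1 pool left out (wild-type replicate 1 or 2, or mutant replicate 1 or 2).

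**Figure D1:**
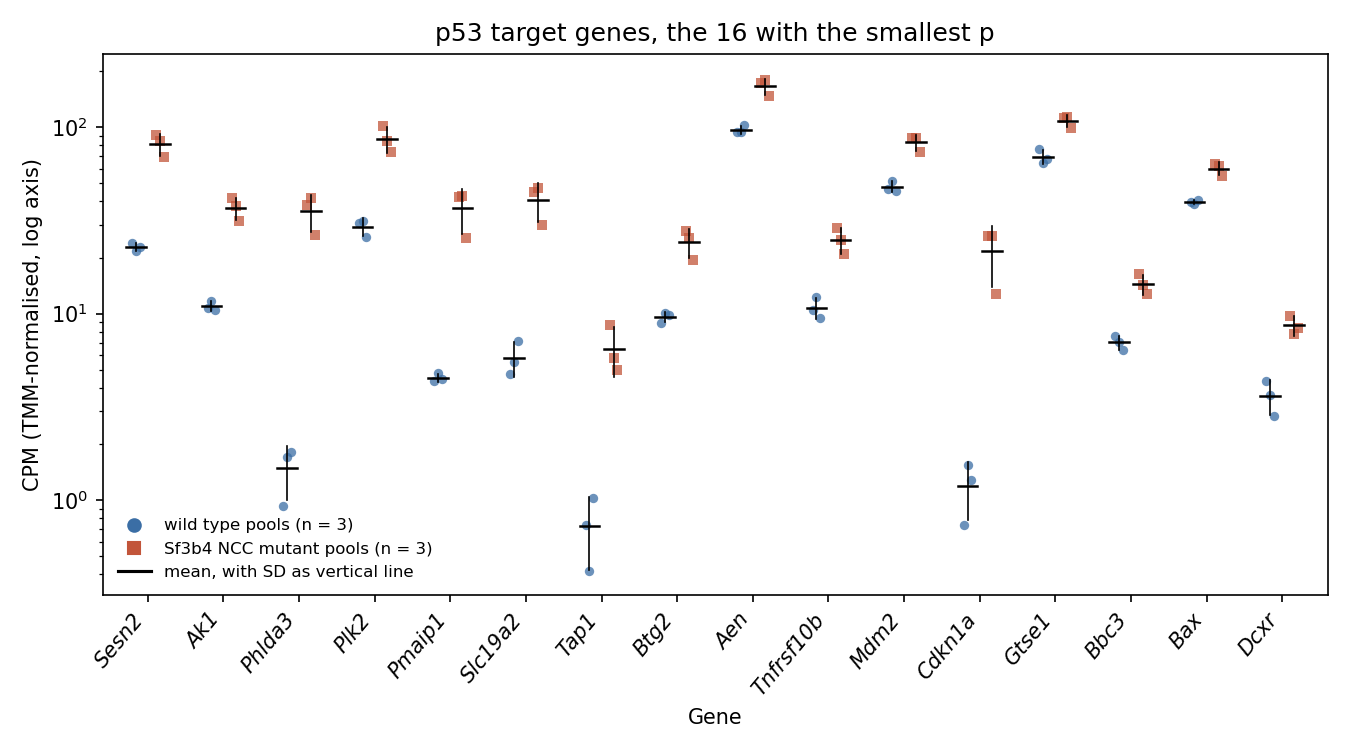
CPM of the 16 p53 target genes with the smallest p in each of the 3 wild-type pools (blue circles) and 3 mutant pools (red squares), on a log axis. Horizontal lines are means and vertical lines SD, and every mutant pool lies above every wild-type pool for each gene, as for Phlda3 (1.48 against 35.4 CPM) and Ak1 (11 against 36.9 CPM).

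Genes of apoptosis followed in part. Of 25 apoptosis effectors 4 rose and 1 fell (5 and 1 when adjusted over the list alone). Tnfrsf10b, a death receptor gene, rose by 1.24 (SE 0.141), while Bmf fell by 0.34. Fas had 3 counts in all wild-type pools together and 52 in the mutant pools, a ratio of 17.3 (95% counting interval 5.61 to 86.8). The list did not pass camera (adjusted p = 0.0913), although it did without mutant replicate 3 (0.0457) and in the 4 pools with Y-linked reads (0.0479), and by fry (fry adjusted p = 0.0341). Among 44 cell cycle genes none rose and 3 fell (5 when adjusted over the list alone), namely Mki67 (-0.44), Ccnd2 (-0.37) and Kif23 (-0.28). The camera adjusted p of the cell cycle list was 0.235. The calls of Bmf, Ccnd2 and Kif23 were lost without wild-type replicate 2 or mutant replicate 1, and those of Bmf and Kif23 without mutant replicate 2 and of Ccnd2 without mutant replicate 3.

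Some neural crest genes were lower in the mutant pools. Of 44 tested neural crest specifiers and markers 8 fell, 1 rose and 35 did not pass (9 and 1 when adjusted over the list alone). Sox10, the transcription factor of migrating crest and glia, went from 47.8 ± 5.92 to 21.6 ± 3.33 CPM, a log2 fold change of -1.15 (SE 0.122, n = 3 pools each, edgeR adjusted p = 5.68e-05). Itga4, an integrin subunit, fell by 1.48 (SE 0.183), Tfap2b by 0.95 (SE 0.137), Ngfr by 0.71 (SE 0.14), Nr2f1 by 0.66 (SE 0.109) and Erbb3 by 0.53 (SE 0.0998). Sox5 (-0.63) and Sox9 (-0.37) also fell, and Foxc1, which is also expressed in head mesoderm, rose (0.37). The calls of Sox10, Itga4, Tfap2b, Nr2f1 and Sox5 held with any 1 pool left out. That of Erbb3 was lost without mutant replicate 1, those of Ngfr and Sox9 without wild-type replicate 2 or mutant replicate 1 and, in turn, mutant replicate 2 and 3. That of Foxc1 (edgeR adjusted p = 0.0497) was lost without wild-type replicate 1 or any 1 mutant pool. It was also lost with DESeq2, limma-voom, library size alone, the fit without robust estimation and the replicate block. The list was lower by camera (adjusted p = 0.00516), and its adjusted p was 0.271 with an estimated correlation. In 31 genes of the crest-derived mesenchyme and pharyngeal arches, Dlx2 (-1.04), Mef2c (-0.76) and Pdgfra (-0.31) fell and 1 gene rose, with 7 lower and 1 higher when adjusted over the list alone. The camera adjusted p of that list was 0.188. The calls of Dlx2, Mef2c and Pdgfra were lost without mutant replicate 2, those of Mef2c and Pdgfra without mutant replicate 1, those of Dlx2 and Pdgfra without wild-type replicate 2, and those of Dlx2 and Mef2c without mutant replicate 3. Wnt1, whose regulatory sequence drives widely used neural crest Cre lines, had a log2 fold change of -0.23 (SE 0.131, edgeR adjusted p = 0.301).

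Some genes that mark the midbrain and its boundary with the hindbrain were lower too. Pax5 went from 47.8 ± 4.12 to 25.8 ± 1.99 CPM, a log2 fold change of -0.89 (SE 0.101, n = 3 pools each, edgeR adjusted p = 7.78e-05), and En1 fell by 0.79 (SE 0.129), Dmbx1 by 0.72 (SE 0.15) and En2 from 18.9 ± 2.44 to 7.89 ± 3.38 CPM. Otx1 fell by 0.45, while Hesx1 (0.64) and Six6 (0.57), which mark the anterior forebrain and eye field, rose. In all, 5 of 29 forebrain and midbrain genes fell and 2 rose, with 5 lower and 6 higher when adjusted over the list alone. Camera found no common direction (adjusted p = 0.956); the median of the list was 0.06 and its mean -0.05. The call of En2 was lost without wild-type replicate 2 or mutant replicate 2, that of Dmbx1 without mutant replicate 1, and those of Otx1, Hesx1 and Six6 without wild-type replicate 2 or any 1 mutant pool (Otx1 also without wild-type replicate 1). Of 27 hindbrain and spinal neural tube genes only Neurod1 changed (3.65, 4 counts in the wild-type pools and 55 in the mutant pools), with 4 higher and 4 lower when adjusted over the list alone and a camera adjusted p of 0.956.

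**Figure D2:**
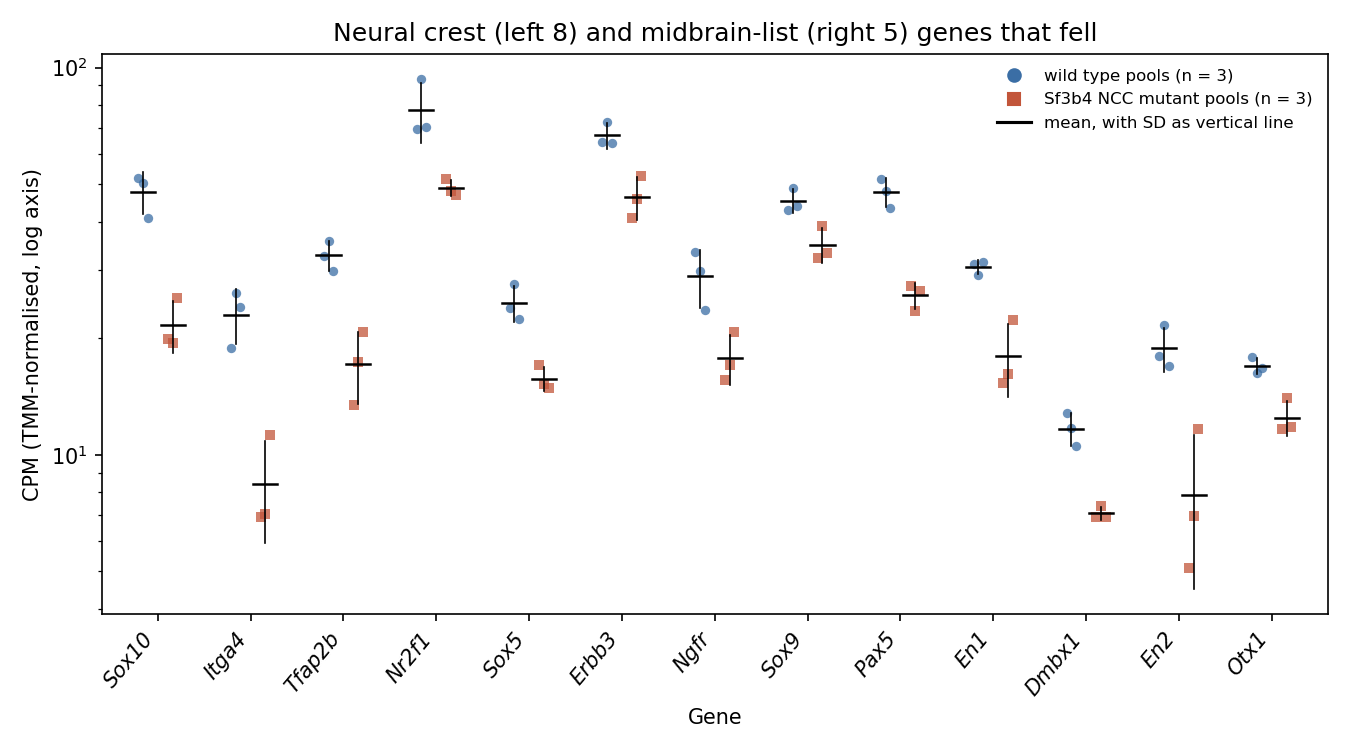
CPM of the 8 neural crest genes and the 5 forebrain and midbrain genes that fell, in each of the 3 wild-type pools (blue circles) and 3 mutant pools (red squares), on a log axis. Horizontal lines are means and vertical lines SD. Sox10 dropped from a mean of 47.8 to 21.6 CPM and Pax5 from 47.8 to 25.8 CPM.

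The list of chromatin modifiers and remodelers leaned lower by camera with its preset correlation, with most genes not past the threshold. Of 94 tested genes 20 fell and 1 rose (32 and 3 when adjusted over the list alone). Smarcc2, a BAF complex subunit, fell by 0.71 (SE 0.0898, n = 3 pools each, edgeR adjusted p = 0.000213), Kdm6b by 0.63, and Kmt2d, Kmt2a, Crebbp, Ep300 and Chd7 by 0.50, 0.52, 0.38, 0.39 and 0.29. Chd5 rose by 1.64 (SE 0.281). The median of the list was -0.15, its camera adjusted p was 1.75e-09, and the adjusted p was 0.271 with an estimated correlation. These genes are long: 58 of the 94 lay in the longest of 5 equal-sized length classes of tested genes. The calls of Kmt2d, Kmt2a, Crebbp, Ep300 and Chd7 were each lost without wild-type replicate 2, mutant replicate 1 or mutant replicate 3. The number of genes of the list that fell was 4 without mutant replicate 1, 4 without mutant replicate 3, 5 without wild-type replicate 2, 5 in the 4 pools with Y-linked reads and 27 without wild-type replicate 3, while the median stayed between -0.174 and -0.135 in every setting but the correction for length and GC content. After that correction 7 fell and 2 rose, with a median of -0.08.

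The lists of surface ectoderm, head mesoderm and endothelium leaned higher by camera with its preset correlation, with few genes past the threshold. Of 23 surface ectoderm and placode genes 6 rose and none fell (12 and 0 when adjusted over the list alone), led by Sp6 (1.08, SE 0.112), a transcription factor of ectodermal organs whose exons overlap those of an opposite-strand transcript over 86.7% of their length. Cldn6 (0.52) and Perp (1.07), which encode epithelial junction proteins, and Cldn7 (0.47) rose with it; the call of Perp, also a p53 target, was lost without mutant replicate 3. Of 19 head and paraxial mesoderm genes 4 rose, among them Fst (0.61, SE 0.0772), Cyp26c1 (0.45) and Foxc1, the same number when adjusted over the list alone. Of 21 genes of endothelium and blood progenitors only Kdr, the VEGF receptor gene, passed (0.31, SE 0.0818; 2 higher when adjusted over the list alone), though 20 of 21 had positive fold changes. The call of Kdr was lost without wild-type replicate 2 or any 1 mutant pool. The camera adjusted p was 3.67e-07 for the ectoderm list, 0.00384 for the mesoderm list and 0.000594 for the endothelium list. It was 0.189, 0.271 and 0.271, as an adjusted p with an estimated correlation. The calls of Cldn7 and Cyp26c1 were lost without wild-type replicate 2 or mutant replicate 1, and each without at least 1 other pool. The mesoderm list did not pass without wild-type replicate 3 (0.121).

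**Figure D3:**
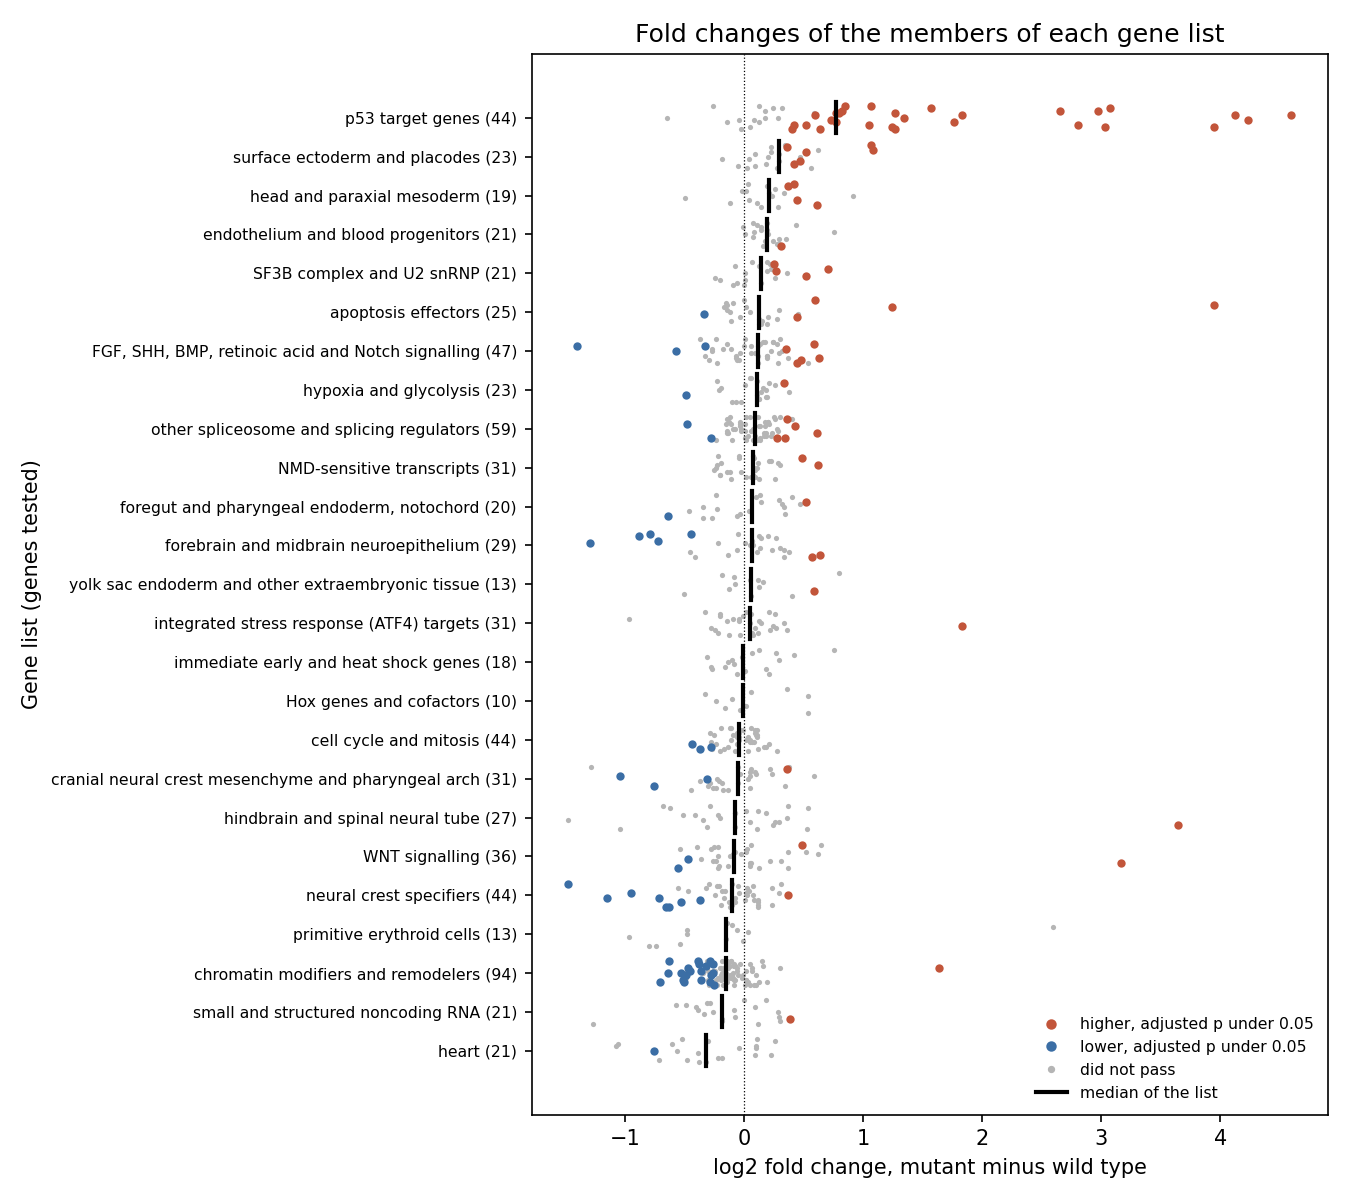
Log2 fold changes (mutant minus wild type) of the tested members of 25 gene lists, 1 dot per gene, with the number of tested genes in brackets. Red and blue dots passed the edgeR test upward and downward, grey dots did not pass, and black bars are list medians, the highest being that of the p53 targets (0.77).

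Several of the other large changes concerned genes with few counts in 1 genotype. Nr1h5, a nuclear receptor gene (chromosome 3, 102939658 to 102964133), had 697 counts in the wild-type pools and 1 in the mutant pools, a ratio of 0.00144 (95% counting interval 3.63e-05 to 0.00802). The pseudogene Rps3a3 fell by 6.34 (SE 0.137), from 163 ± 15 to 2.02 ± 0.43 CPM; its near-identical copy Rps3a1 can share its reads. Cdh19, a cadherin gene of Schwann cell precursors, fell by 1.99 (SE 0.274), from 6.73 ± 2.11 to 1.65 ± 0.156 CPM, and Cdhr2 by 2.39 and Cnmd by 2.26. Upward, Ltb4r2, a leukotriene receptor gene, had 3 counts in the wild-type pools and 109 in the mutant pools, a ratio of 36.3 (95% counting interval 12.1 to 179). Ddit4l, an inhibitor of mTOR signalling, rose by 3.72 (SE 0.22), Ptprv by 4.05 (SE 0.419), Lif, the cytokine gene, by 3.39 (SE 0.614), Sfrp4, a secreted WNT antagonist gene, by 3.17 (SE 0.543) and Tap1, a peptide transporter gene that is also on the p53 list, by 3.08 (SE 0.323). All of these calls held with any 1 pool left out. Counting intervals cover counting error only.

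In signalling pathways the changes went both ways. Of 36 WNT pathway genes 2 rose (Sfrp4 and Frzb, 0.48) and 2 fell (Apcdd1, -0.56, and Tcf7l1, -0.47); 2 and 4 did when adjusted over the list alone, and the camera adjusted p was 0.405. Of 47 genes of FGF, SHH, BMP, retinoic acid and Notch signalling 5 rose and 3 fell (8 and 4 when adjusted over the list alone), among them Aldh1a3 (-1.41), a retinoic acid synthesis gene, the Notch target Hes5 (-0.57), the FGF feedback gene Dusp6 (0.35) and the BMP antagonist gene Grem1 (0.63). The camera adjusted p was 0.19, and the list passed without wild-type replicate 1 (0.0334) and in the 4 pools with Y-linked reads (0.0161). Only Sesn2, also a p53 target, passed among 31 targets of ATF4 in the integrated stress response (1 when adjusted over the list alone; camera adjusted p = 0.625). Of 31 transcripts sensitive to nonsense-mediated decay Snhg15 (0.49) and Snhg1 (0.62) rose and none fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.544). The calls of Tcf7l1, Hes5, Dusp6, Grem1, Snhg15 and Snhg1 were lost without mutant replicate 1, and all but that of Dusp6 without at least 1 other pool.

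The remaining lists showed 1 or 2 changed members or none. None of 10 Hox genes and cofactors passed (2 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.956). Among 23 genes of hypoxia and glycolysis Slc2a3 rose (0.33) and Pdk1 fell (-0.49), the same when adjusted over the list alone. The camera adjusted p of 0.188 became 0.000455 without wild-type replicate 1 and 0.0117 in the 4 pools with Y-linked reads. Without wild-type replicate 2 the list had the opposite direction (0.969), and with an estimated correlation the adjusted p was 0.905. In 20 genes of foregut and notochord Cldn6 rose and Trh fell (1 and 2 when adjusted over the list alone; camera adjusted p = 0.886). Of 13 yolk sac and extraembryonic genes 1 rose and none fell (camera adjusted p = 0.705), of 21 small structured RNAs only Rn7sk (0.39; 2 when adjusted over the list alone; camera adjusted p = 0.625), and none of 18 immediate early and heat shock genes passed (camera adjusted p = 0.896). Of 21 heart genes only Mef2c passed, with a list median of -0.32 and a camera adjusted p of 0.405. The heart list passed downward without wild-type replicate 3 (1.42e-05) and had the opposite direction without wild-type replicate 1. None of 13 primitive erythroid genes passed (camera adjusted p = 0.341; 0.000532, lower, without wild-type replicate 1; 0.000708, lower, in the 4 pools with Y-linked reads). For the extraembryonic, immediate early, heart and erythroid lists the count adjusted over the list alone was the same as over all genes. The calls of Slc2a3, Pdk1, Trh and Rn7sk were lost without mutant replicate 1, and each without at least 1 other pool. The mitochondrially encoded genes are listed at 0 in every pool and none was tested.

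Near the deleted gene, 10 of 109 tested genes within 5 Mb of Sf3b4 changed (9.17%), against 6.5% elsewhere, an odds ratio of 1.45 (Fisher's exact test, two-sided, p = 0.242). Within 10 Mb it was 28 of 254 genes, an odds ratio of 1.80 (Fisher's exact test, two-sided, p = 0.00652), and within 1 Mb 4 of 61 genes, an odds ratio of 1.01. Xist was read at 426 ± 190 CPM in the wild-type and 286 ± 76.5 CPM in the mutant pools, and the Y-linked Ddx3y at 8.16 ± 7.13 and 9.14 ± 7.94 CPM; neither they nor any of the 5 tested sex-linked genes passed, before or after adjustment over the list alone.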

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

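Y-linked reads as a covariate, the pools with Y-linked reads alone and the correction for length and GC content were chosen after seeing the data; the other alternatives were planned. The 914 changed genes became 694 to 1363 with other tools, scalings, filters, the fit without robust estimation and the replicate block, and every one of the 914 that was tested kept its sign. DESeq2 called 772 genes, 689 of them shared, and limma-voom 732, 719 of them shared. With no filter on low counts 624 genes were higher, with 28032 genes tested, and an adjusted p under 0.1 gave 1550 changed genes. With 1 pool left out, the count ranged from 230 to 1810, the higher genes from 107 to 890 and the lower genes from 123 to 920. Fewer pools lower the power, but the rise to 1810 came without wild-type replicate 3, and the cause was not tested. With Y-linked reads as a covariate 1616 genes changed (739 higher, 877 lower), and in the pools with Y-linked reads alone 535 (286 lower), with fewer pools. The correction for length and GC content gave 655 higher genes. Changed list members, 112 in all, numbered 54 to 158 with 1 pool left out (70 without wild-type replicate 2, 54 and 71 without mutant replicates 1 and 3) and 173 with the Y-linked covariate. Of the 8 lists past the camera threshold none passed with an estimated correlation (0 lists). By fry 7 of the 8 passed, without the other splicing genes (0.346), and apoptosis effectors passed as well (0.0341). Sf3b4 had a log2 fold change of -0.32 to -0.17 over 19 alternatives, with adjusted p from 0.0288 to 0.441 by the tool of each; it passed without wild-type replicate 3 (-0.32, adjusted p = 0.0288) and with the length and GC correction (-0.26, adjusted p = 0.0447), and the cause was not tested. The odds ratio for genes near Sf3b4 was 1.80 in the 10 Mb window (Fisher's exact test, p = 0.00652). Of 116 genes chosen by the rule or as examples that passed, 54 passed in every alternative that gave a value, 85 in every one that leaves out no pool, and none changed sign; 56 calls were lost without mutant replicate 1, 41 and 39 without mutant replicates 2 and 3, and 16, 40 and 6 without wild-type replicates 1 to 3. The Sf3b2 log2 fold change, which did not pass, changed sign with library size alone (-0.0209) and ranged from -0.051 to 0.0706 with 1 pool left out. The Ddx3y log2 fold change, of a gene read only in pools with Y-linked reads, ranged from -0.34 to 0.98. The data gave no sign that the replicate numbers pair the pools. Deviations of same-numbered pools correlated at -0.179, 0.0865 and -0.0716 across genes, and no pool correlated best with its own number. The highest correlation (0.302) joined wild-type replicate 1 and mutant replicate 3, the pools almost without Y-linked reads. A weaker pairing could be hidden by this, so the check cannot exclude it. The fit with the replicate block called 694 genes, 660 of them shared, and 9 lists, adding the heart list (adjusted p = 0.0167), which is not read as evidence of an effect. Depth limits the low genes: Fas and Ltb4r2 rest on 3 wild-type counts each.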

Other observations

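Gene families defined by their symbols were examined after the changed genes had been seen, with 30 two-sided Fisher's exact tests over protein-coding genes, adjusted together. Since the same genes prompted the choice of families, the p values only describe the families and are not an independent test of them. Of 15 families 9 passed. Cep genes, cytosolic and mitochondrial ribosomal proteins, respiratory chain subunits, proteasome subunits and protocadherins did not (adjusted p from 0.154 to 1, Fisher's exact test). The test counts called genes, so it does not show these families to be unchanged. Fold changes were positive in 79 of 81 cytosolic ribosomal proteins (median 0.164), 74 of 85 respiratory chain subunits (0.151) and 5 of 33 protocadherins (-0.28). They were positive in 56 of 77 mitochondrial ribosomal proteins, 29 of 37 proteasome subunits and 10 of 35 Cep genes. A common direction was not tested. Among 7 S100 calcium-binding protein genes 3 rose (S100a6, S100a10 and S100a11; adjusted p = 0.00703, Fisher's exact test), as did 3 of 13 claudins (Cldn4, Cldn6 and Cldn7; adjusted p = 0.0255, Fisher's exact test). Of 345 zinc finger genes with Zfp symbols 231 had positive fold changes, 11 rose and only 3 fell, fewer falls than among other genes (adjusted p = 0.00703, Fisher's exact test); 18 rose and 6 fell after the correction for length and GC content. Of 64 kinesins, dyneins and myosins 12 fell and none rose (adjusted p = 3e-04, Fisher's exact test), and 11 fell after the correction, while the family median went from -0.132 to -0.054; they include Kif14, Kif15 and Kif23, which act in mitosis, and the dynein heavy chains Dync1h1 and Dync2h1. Of 21 nucleoporins 4 fell (Nup107, Nup155, Nup188 and Nup210; adjusted p = 0.0409, Fisher's exact test), and 4 fell after the correction. Of 36 Fanconi, Brca and Rad repair genes 6 fell, among them Brca2, Bard1 and Fanci (adjusted p = 0.0196, Fisher's exact test), and 5 fell and 2 rose after the correction. In contrast, 9 of 62 semaphorin, plexin, ephrin, Slit, Robo, netrin and Unc5 genes fell and 3 rose (adjusted p = 0.00703 for the falls, Fisher's exact test), but 6 fell and 6 rose after the correction, and the family median went from -0.121 to 0.001. Of 60 Dock, Arhgef and Arhgap genes 7 fell (adjusted p = 0.0409, Fisher's exact test), and 6 fell and 2 rose after the correction. Of 47 genes of collagens, laminins and matrix 6 fell (adjusted p = 0.0409, Fisher's exact test), and 3 fell and 2 rose after it. Of the genes named here, the calls of S100a10, Cldn6, Kif15 and Dync2h1 held with any 1 pool left out, and those of the others were lost without mutant replicate 1.

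The tests of the chromatin correction, of the shared Rps3a reads, of the genome windows (after the 10 Mb window had been tested) and of the crest and midbrain pattern were chosen after the results were seen; those of the splits, the matched lists and the exon number were written down before their results. The 6 pools allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 914 genes and the highest other split 2. For higher genes it gave 371 against 1, and for lower genes 543 against 1, so 1 of 10 splits gave as many in each case. For gene lists 5 of the 10 splits passed as many lists by camera as the real one, which passed 8, and the highest other split passed 10. Each other split mixes the genotypes, so differences between pools of a genotype, or an uneven effect among the mutant pools, may pass lists as well, and the set test with its preset correlation does not single out the genotype.

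Lower genes were long: the median exon length was 7901 bases among the 543 genes that fell, 3642 among the 371 that rose and 4354.5 among all tested genes. The rank correlation of fold change with length was 0.265 in size in the real split and up to 0.301 in the others. Since the other splits mix the genotypes, this does not separate a length trend from the genotype. Each pool's deviations from the mean of all pools correlated with length at 0.0461, 0.369 and 0.0824 in the wild-type pools. In the mutant pools the correlations were -0.161, -0.0954 and -0.343. The sign of the trend thus differed between the genotypes, and among the wild-type pools it was strongest in replicate 2 (0.369). Deviations from a common mean cancel over the pools, so opposite signs in the genotypes are partly built in. Length-dependent recovery of RNA remains a candidate source of the fall of chromatin modifiers. The list still passed camera after the correction (adjusted p = 0.00315), but 4.98% of 10000 random lists matched on length and GC content had a median as low, which is within their central 95% range (-0.16 to -0.06), so a fall beyond that of other long genes was not shown. At equal length, GC content and expression, genes with more exons fell more (partial rank correlation -0.199 across protein-coding genes, which are not independent replicates). The largest correlation in the other 9 splits was 0.148 in size. Those splits mix the genotypes and are too few for a share under 0.05, so this comparison is not independent support. A weaker output of genes with many introns may contribute, as a hypothesis. Transcript integrity and intron retention were not analysed here.

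Rps3a3 and Nr1h5 were almost absent from the mutant pools. For Rps3a3, reads shared with its parent gene are a candidate explanation: 67.2% of its 31-base words occur in Rps3a1 (chromosome 3, 86137940 to 86142702), which went from 876 ± 68.4 to 1396 ± 24 CPM while Rps3a3 lost 161 CPM. The 3 copies together still went from 1053 ± 83.2 to 1404 ± 23.8 CPM. If all shared reads were counted, moved reads do not account for the whole rise of Rps3a1. How reads that match more than 1 copy were counted is not given in the sources used here, so the sum cannot decide this. Nr1h5 lies 6.8 Mb from Sf3b4. A different haplotype around Sf3b4 in the mutant pools stays open: 1.58% of genome windows of 254 consecutive tested genes held as many changed genes as the 10 Mb window around Sf3b4, which had prompted this test, but the odds ratio was 1.45 within 5 Mb (Fisher's exact test, p = 0.242) and 1.01 within 1 Mb (Fisher's exact test, p = 1). Near-absence from 1 genotype was not confined to this region, but among 4 predicted genes it was mostly from the wild-type pools. Gm43803 (chromosome 3, 43.1 Mb from Sf3b4), Gm12666 and Gm13067 (both chromosome 4) held 0, 0 and 1 counts there. In the mutant pools they held 91, 192 and 69. Only Gm44341 (chromosome 13) went the way of Nr1h5, with 70 counts in the wild-type pools and 0 in the mutant pools. Strain backgrounds are not given in the sources used here, and an effect of the deletion on these genes stays open.

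Crest, arch and midbrain genes that fell did so by a median of -0.74 (16 genes). A different posterior limit of the dissected heads would move hindbrain and Hox genes together. The median of 12 such genes did not decide the question (0.269, 95% bootstrap interval -0.03 to 0.491). The bootstrap intervals in this paragraph resampled genes, not pools, so they do not measure the spread between pools. Cochran's Q, used next, treats genes read in the same pools as independent. A smaller share of crest cells, with each gene at an unchanged level and expressed nowhere else, would give the crest genes 1 common fold change, but those of Sox10, Foxd3, Erbb3, Ngfr, Tfap2b, Itga4 and Cdh19 ranged from -1.99 to -0.53 and differed beyond their errors (Cochran's Q = 48.8 on 6 degrees of freedom); fewer crest cells together with expression elsewhere, or lower levels per cell, may both contribute. The lists of other tissues had medians of 0.29 for surface ectoderm, 0.207 for head mesoderm and 0.191 for endothelium. Medians were -0.317 for heart and -0.148 for erythroid cells, but neither list passed camera (adjusted p = 0.405 and 0.341). Nor did these 2 keep their direction. The heart median was -0.563 between the pools without Y-linked reads and 0.0543 among those with them, and the erythroid median 0.459 and -0.425. A changed mix of tissues in the heads stays open as well. Younger mutant embryos cannot be told apart from an effect of the deletion, since 18 neuronal differentiation genes had a median of -0.253 with an interval of -0.52 to 0.02 and somite numbers are not given in the sources used here. A change in the crest cells that lack Sf3b4 stays open as a biological explanation for the crest genes. Whether it could also account for the fall of the midbrain genes was not tested.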
